A study of Daphnia magna with 24 samples.

How the data were processed

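Gene expression was measured in pools of 8 Daphnia magna neonates after 12 h with 0, 7.8, 31.2, 125, 500 or 2000 pM emamectin benzoate, with 4 biological replicates in each of 6 groups per the labels. Total RNA was labelled with Cy3 and hybridised to 24 single-colour Agilent arrays of 62976 spots. The authors quantified the scanner images with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 per the file headers. The deposited scanner files hold spot intensity that is not normalized between arrays, per the file headers: the processed signal, in which the software subtracted the background, and the median signals of spot and background, with flags per spot. The authors' series table holds, for 50432 probes, a linear ratio; how it was made is not given in the sources used here. On the log2 scale it correlated with quantile-normalized processed signals minus each probe's median over the arrays (r = 0.99989 over all values), and with values scaled to the 75th percentile at r = 0.979, so that scale, centring and direction were settled from the values; the rule by which its probes were selected was not. Its column medians lie between 0.975 and 1.06. It was used as an alternative only.

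From the scanner files, control spots and spots flagged as outliers (17 to 264 per array) were left out, no non-control spot was saturated, and spots of 1 probe were averaged. Values are log2 of the processed signal minus the array's 75th percentile over the 61207 non-control probes. Probes well above background on at least 4 of the 24 arrays, whatever their group, were kept, which left 54920. Group means were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (figures with matplotlib 3.10.9 in Python 3.11.15). Each concentration was contrasted with the control, as were the highest with the lowest and neighbouring concentrations. The trend was the slope on the order of the groups, and the F test covered the 5 contrasts with the control. All limma tests were two-sided with Benjamini-Hochberg adjustment over all probes of a contrast and a threshold of 0.05. The number of arrays limits the precision. Group designs, tests, the alternatives named in the closing section as planned, and the rule for the probes named were fixed before the data were examined. As the files do not pair probes with genes and 0 identifiers matched the RefSeq gene table, that rule named the 2 largest rises and the 2 largest falls at 2000 pM among called probes whose 4 exposed arrays all lay on 1 side of the control mean (6318 of 6353 probes). For the same reason the 27 planned gene lists and their set tests were not run.

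The same functions were tested on simulated data: arrays drawn from the real probes' means and residual SDs with 200 of 54920 probes changed by known folds. For 2000 pM against the control, 34% of 1.5-fold, 52% of 2-fold, 72% of 3-fold and 84% of 4-fold changes were found, all in the right direction, with 7 false calls. Noise was drawn independently for each probe and array, without differences between slides, and the share found depends on how many probes change. These shares therefore hold for such arrays and may differ for the real ones.

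The slide of each array was read from the file headers, giving 3 slides of 8 arrays. The 31.2 and 500 pM groups lay on slide 3 alone, so contrasts within slides 1 and 2, contrasts with the slide as a fixed or random block, and the contrast of 500 with 31.2 pM inside slide 3 were computed as well; the last of these was chosen after the data had been seen. Within-slide scores were compared by exact permutation within slides, one-sided because the direction was set by other slides. Shared calls were compared with independent lists, with 50 simulated sets of unchanged groups drawn from whole-array residuals, and with the controls split 2 against 2.

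Alternatives were normexp background correction (offset 50) in place of the software's, quantile or median normalization, the authors' table, no filter or a filter on all 24 arrays (41327 probes), the replicate number as a block, the slide as a block, array weights, only the 8 arrays compared, 1 probe per contig, other concentration scales and leaving out each array. The mean spot signal was not among the columns used, so normexp was run on the median spot signal. A single probe per gene was replaced by 1 probe per contig.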

Results

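Neonates of the freshwater crustacean Daphnia magna were kept for 12 h in water holding emamectin benzoate at 7.8, 31.2, 125, 500 or 2000 pM, or in water without it. Emamectin benzoate is an avermectin insecticide; avermectins open glutamate-gated chloride channels in the nerves and muscles of arthropods. Each sample was total RNA from a pool of 8 whole animals, and each of the 6 groups had 4 biological replicates, so that 24 samples were each hybridised to 1 Agilent array in a single colour (Cy3). The question set by the series is which transcripts change after this short exposure, and from which concentration. Each array carried 61207 different non-control probes for 58904 assembled transcript contigs. Between 73.3% and 90.4% of these probes were well above background on an array, and the 75th percentile signal of an array lay between 476 and 1089 intensity units. The files pair probes with contig names, not with genes, and 0 of these identifiers matched the gene table used here, so that transcripts are given below by probe and contig identifier, and the gene groups chosen in advance could not be described.

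The arrays lay on 3 slides of 8 arrays. Slides 1 and 2 each held 2 arrays of the control, 7.8, 125 and 2000 pM groups. Slide 3 held all 4 arrays of 31.2 pM and all 4 of 500 pM and no control. The contrasts of 7.8, 125 and 2000 pM with the control can therefore be made within slides, whereas in the contrasts of 31.2 and 500 pM with the control the slide and the group cannot be told apart. The 31.2 and 500 pM groups can be compared with each other within slide 3. Between slides 1 and 2, with the group held, 1843 of 54920 probes differed by limma's moderated test (Benjamini-Hochberg adjusted p under 0.05).

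Of the concentrations that shared slides with the control, only the highest had probes called in the fit to all 24 arrays. At 2000 pM, 6353 of the 54920 probes tested (11.6%) passed the threshold of limma's moderated test against the control, 3025 higher and 3328 lower. Most changes were small: the median size among the changed probes was 0.49 on the log2 scale (1.4-fold), and 605 probes changed by more than 2-fold, 395 upward and 210 downward. More than 4-fold changes were found for 39 probes that rose and 21 that fell. Changed probes were found at all signal levels, from 2.78% of the 13730 dimmest probes to 18.6% of the 13730 brightest. With the slide as a block, and slides 1 and 2 alone, 5978 probes were called, and with only the 8 arrays of both groups in the fit 3196. Within slide 1 alone (2 arrays per group) 16 probes were called and within slide 2 alone 0, while 7941 and 6944 probes had an unadjusted p under 0.05.

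The largest rise belonged to probe CUST_11897_PI429451402, which reads contig Dm_BP_CL2321.Contig1. Its log2 signal relative to the array's 75th percentile was -0.38 ± 0.24 (SD, n = 4) in the controls and 4.64 ± 0.59 (SD, n = 4) at 2000 pM, a log2 change of 5.03 with a standard error of 0.32 (32.6-fold; limma adjusted p = 1.5e-08). Probe CUST_27564_PI429451402, for contig Dm_BP_Unigene14245, rose from -1.53 ± 0.98 (SD, n = 4) to 3.14 ± 1.01 (SD, n = 4), a log2 change of 4.67 with a standard error of 1.02 (limma adjusted p = 0.00411). This probe also varied widely among arrays of a single group, with an SD of 2.09 at 125 pM. With the 75th percentile scaling, the largest fall was that of probe CUST_55351_PI429451402 for contig Dm_BP_Unigene22730, from -1.73 ± 0.23 (SD, n = 4) to -5.24 ± 0.9 (SD, n = 4), a log2 change of -3.52 with a standard error of 0.4 (limma adjusted p = 1.43e-05). Its signal at 2000 pM was well above background on only 2 of the 4 arrays, so that the size of its fall is uncertain: with normexp background correction the log2 change was -1.6 (limma adjusted p = 2.62e-05), smaller than that of the next probe. Probe CUST_14938_PI429451402 for contig Dm_BP_CL3589.Contig1 fell from 1.85 ± 0.27 (SD, n = 4) to -1.11 ± 0.66 (SD, n = 4), a log2 change of -2.96 with a standard error of 0.4 (limma adjusted p = 7.86e-05; -2.65 with normexp).

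**Figure D1:**
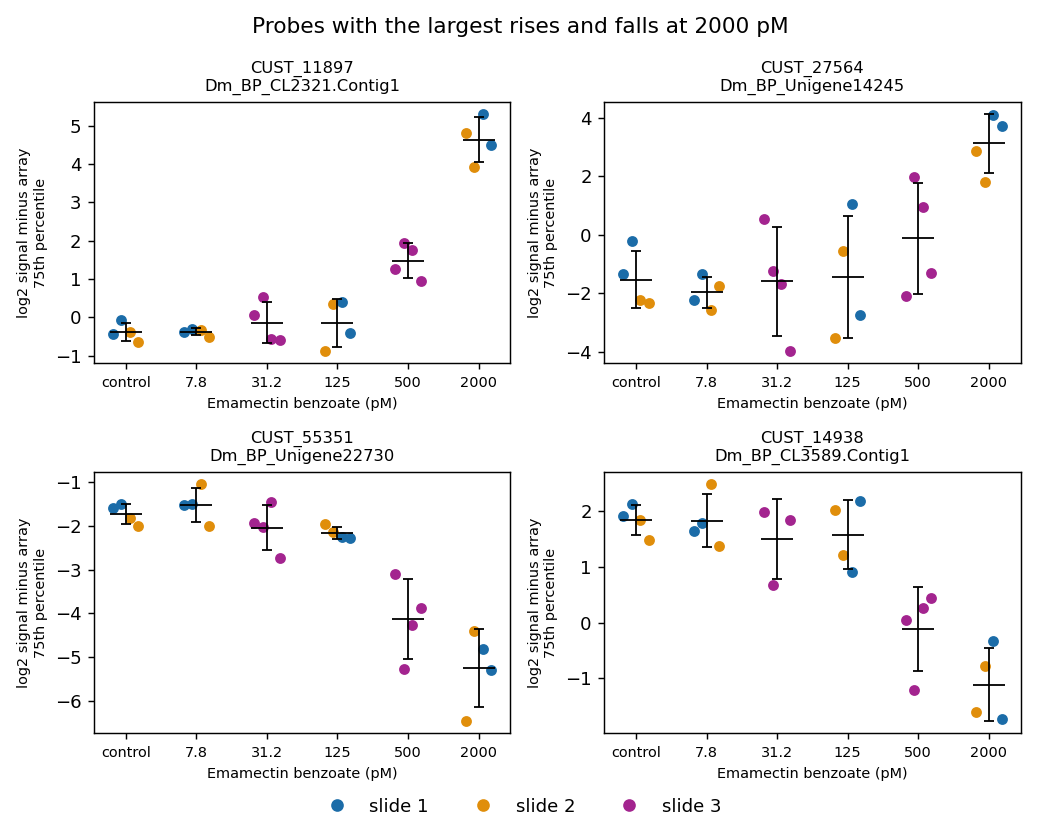
Log2 signal minus the array's 75th percentile for the 2 probes with the largest rises (top) and the 2 with the largest falls (bottom) at 2000 pM, against the concentration of emamectin benzoate. Points are single arrays coloured by slide and bars are the group mean with its SD. CUST_11897 rose from a mean of -0.38 in the controls to 4.64 at 2000 pM, with 1.48 at 500 pM.

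The change at 2000 pM was seen separately on both slides. The 400 probes that changed most on slide 1 (200 in each direction, by the moderated test on that slide) were looked up on slide 2, which shares no array with it. Of these, 388 (97%) moved in the same direction on slide 2, with a Pearson r of 0.912 across probes; in the opposite direction, 374 of the 400 probes chosen on slide 2 moved the same way on slide 1 (93.5%, r = 0.866). Over all probes tested, most of which were not called, r between the slides was 0.268. Probes are not independent replicates, so these correlations describe the arrays and carry no p-value. Contigs read by 3 probes gave a check of the probes against each other, not of the response. The 3 read the same RNA on the same arrays, so they would also move together in a chance difference between pools. Of 967 such contigs, 261 had at least 1 probe changed at 2000 pM. In 249 of these the log2 changes of all 3 probes had the same sign. In all 97 contigs with 3 changed probes, the 3 moved in the same direction.

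At the lowest concentration, 7.8 pM, and at 125 pM, no probe passed the threshold of limma's moderated test against the control. At an unadjusted p under 0.05 there were 2674 probes (4.87% of those tested) at 7.8 pM and 1572 (2.86%) at 125 pM. At 7.8 pM this unadjusted count depended on the arrays in the fit: it was 4467 without 500 pM replicate 1 and 5210 with only the 8 arrays compared. With the slide as a block in slides 1 and 2, the counts past the adjusted threshold stayed 0 at both concentrations, with 3846 and 1908 probes under an unadjusted 0.05, and they were 0 within each of these slides too. In simulated arrays with 200 changed probes among 54920 at 7.8 pM, the same test found 24% of the 1.5-fold changes, 62% of the 2-fold changes and 90% of the 4-fold changes. At 125 pM it found 32%, 66% and 86%. The simulated arrays had independent noise for each probe and no slide differences, so these shares may differ for the real arrays. The 4 probes named above differed from the controls by at most 0.44 on the log2 scale at 7.8 and 125 pM, with limma adjusted p-values of 0.954 or more. The direct comparison of 125 with 7.8 pM called 0 probes by limma, with 4566 at an unadjusted p under 0.05.

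At 31.2 pM, 2190 probes differed from the control by limma's moderated test, 680 higher and 1510 lower, and at 500 pM 4398 differed, 2009 higher and 2389 lower. The count at 31.2 pM ran from 1180 without control replicate 2 to 3637 without 500 pM replicate 1, with 7 of the 24 arrays each moving it by over 1.5 times, and it was 5863 with array weights. The count at 500 pM was 340 with only the 8 arrays compared and 19643 with normexp background correction. These contrasts compare slide 3 with slides 1 and 2. With the slide as a random block the counts were 2965 at 31.2 pM and 5433 at 500 pM. The correlation within slides in that fit was -0.0382, so it made no allowance for a difference of slide 3. The share of higher probes among those called also moved with the scaling: at 31.2 pM it was 31.1% with the 75th percentile, 43.5% with quantile normalization and 50.4% with the median, and at 500 pM it was 45.7%, 54.1% and 61.3%. With normexp background correction it was 22.3% at 31.2 pM and 15% at 500 pM, and that correction moved the median of all probes at 500 pM to -0.17 on the log2 scale. Spike-in RNA, which is added to every labelling reaction and does not come from the animals, differed along the same line. The 6 E1A spike-in sequences that were bright on every array were higher relative to the 75th percentile on slide 3, by 1.11 on the log2 scale, and their means ran from 2.71 to 3.18 on the 8 arrays of slide 3 and from 1.53 to 2.09 on the 16 others. Between 2000 pM and the control, whose arrays shared slides, the spike-ins differed by -0.195.

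**Figure D2:**
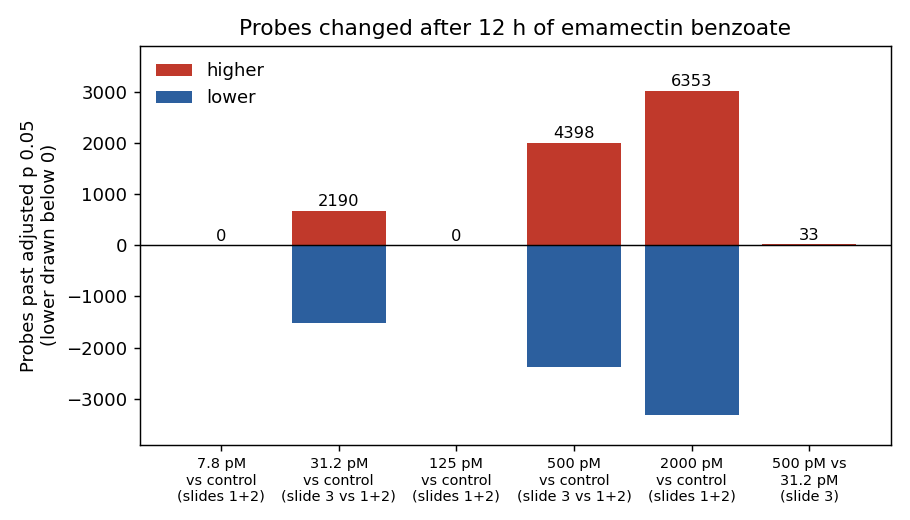
Number of probes past an adjusted p of 0.05 in limma's moderated test for each concentration against the control and for 500 against 31.2 pM; probes that were higher are drawn above 0 and lower ones below, with the total printed above each bar. The slides compared are given under each bar: the 6353 probes called at 2000 pM, from the fit to all 24 arrays, compare arrays that shared slides with controls, while 31.2 and 500 pM were compared with controls on other slides.

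**Figure D3:**
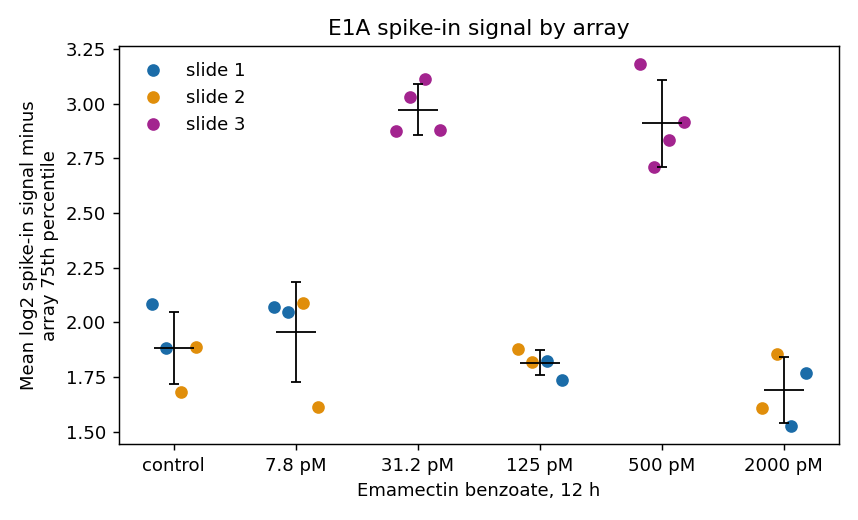
Mean log2 signal of the E1A spike-ins minus the array's 75th percentile, for every array by group, coloured by slide; bars are group means with their SD. The 8 arrays of slide 3 lie between 2.71 and 3.18 and the others between 1.53 and 2.09.

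The 500 and 31.2 pM arrays shared slide 3, although their 75th percentile signals did not overlap (691 to 830 intensity units at 31.2 pM and 889 to 1089 at 500 pM). Between them 33 probes differed by limma's moderated test, 23 higher and 10 lower at 500 pM. That split moved with the scaling, to 22 higher and 52 lower with normexp and 9 higher and 1 lower with the median. The count itself rested on single arrays, from 4 without 31.2 pM replicate 4 to 75 without 500 pM replicate 1, and it was 277 with array weights. All 33 of the fit to all arrays were also called at 2000 pM against the control in the same direction, a contrast of other arrays that called 11.6% of the probes tested. Both contrasts took each probe's residual variance from the same fit, which favours probes of low variance in both, and in the 8 arrays of slide 3 alone 2 probes were called. Across the 6353 probes changed at 2000 pM, 5517 (86.8%) differed between 500 and 31.2 pM in the same direction as at 2000 pM, with a slope of 0.307 on the 2000 pM change (r = 0.767). Without 500 pM replicate 1 the share was 80.2% and the slope 0.296 (r = 0.685). Over all 54920 probes, with every array kept, the share was 58.1% and the slope 0.0999 (r = 0.112). A contrast without calls can also stray from an even share: between 125 and 7.8 pM, 33.6% of the same 6353 probes moved in the direction of 2000 pM (r = -0.285). Probes that rose at 2000 pM were higher at 500 than at 31.2 pM by 0.226 on average on the log2 scale, and those that fell were lower, by a mean of -0.121. The 4 named probes moved the same way: CUST_11897_PI429451402 was 3.07-fold higher at 500 than at 31.2 pM and CUST_55351_PI429451402 was 4.25-fold lower, although neither difference passed the limma threshold on its own (adjusted p = 0.061 and 0.0559). For CUST_27564_PI429451402 and CUST_14938_PI429451402 the log2 differences were 1.47 with a standard error of 1.02 and -1.61 with a standard error of 0.44 (limma adjusted p = 0.768 and 0.258).

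A single score per array summarised how far it lay along the response to 2000 pM. It was the mean of the 200 probes that rose most minus the mean of the 200 that fell most at 2000 pM, divided by 2, with the probes always chosen on other slides than the array's own; this measure was added after the data had been seen. Relative to the controls of the same slide, the 2000 pM arrays scored 0.972 ± 0.096 (SD, n = 4), against 0 ± 0.03 in the controls (exact permutation within slides, one-sided p = 0.0278, the smallest that the 36 arrangements allow; adjusted over the 4 comparisons of this kind 0.0371). On slide 3, the 500 pM arrays scored 0.37 ± 0.119 (SD, n = 4) above the mean of the 31.2 pM arrays, which spread by 0.097 (exact permutation, one-sided p = 0.0143, the smallest of 70 arrangements; adjusted 0.0371). All 4 of the 500 pM arrays, between 0.204 and 0.463, lay above all 4 of the 31.2 pM arrays, between -0.141 and 0.065. The 7.8 pM arrays scored 0.125 ± 0.085 (SD, n = 4; exact permutation within slides, one-sided p = 0.0278, adjusted 0.0371), and all 4 lay above the highest control, at 0.031; without the 2000 pM replicate 2 array the difference was 0.019, and the call depended on single arrays. It was also lost with quantile normalization (exact p = 0.0833) and with 50 or 1000 probes per direction (exact p = 0.0556 in both). The 125 pM arrays scored 0.051 ± 0.047 (SD, n = 4; exact permutation within slides, one-sided p = 0.0833, adjusted 0.0833), and without control replicate 4 the sign turned, to -0.053. The contrasts of 7.8, 125 and 2000 pM share the same controls. Scores were centred on the mean of the 2 controls of each slide, so the control scores mirror each other around 0. Their spread of 0.03 and the highest control score are therefore too small to set beside the spread of an exposed group. Leaving out single arrays moved the 2000 pM score to between 0.6 and 0.993.

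**Figure D4:**
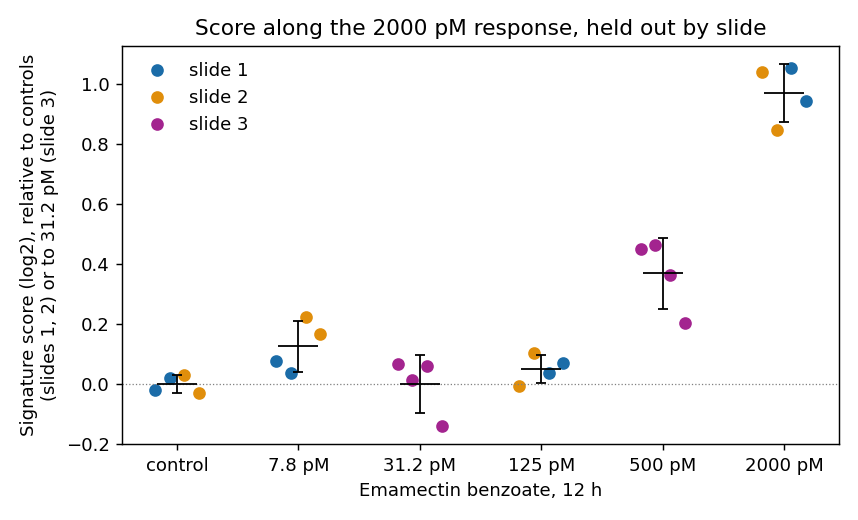
Score of each array along the 2000 pM response (log2 units), by group and coloured by slide, with the group mean and SD. Scores are relative to the controls of the same slide on slides 1 and 2 and to the 31.2 pM mean on slide 3: the 2000 pM mean is 0.972, the 500 pM mean 0.37 and the 7.8 pM mean 0.125.

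Using all 6 groups in order, 4369 probes had a slope across the concentration steps by limma's moderated test, 2310 rising and 2059 falling with concentration. Within slides 1 and 2, with the slide as a block, 2546 probes had such a slope, 1382 rising and 1164 falling; with the slide as a block over all 24 arrays, 5809 did. Without the 2000 pM replicate 1 array the count over all arrays was 2659. A slope can be called where only the 2000 pM group differs. In the same block fit of slides 1 and 2, 5978 probes were called at 2000 pM against the control and 0 at 7.8 and 125 pM. The trend counts therefore do not show a graded change. The F test for a difference between any concentration and the control called 10896 probes over all arrays. Within slides 1 and 2 with the slide as a block it covered only 7.8, 125 and 2000 pM and called 4638.

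The highest and the lowest concentrations differed directly: 4602 probes were called between 2000 and 7.8 pM, 2320 higher and 2282 lower at 2000 pM, by limma's moderated test. With slides 1 and 2 alone and the slide as a block the count was 4026, and without 2000 pM replicate 1 it was 2970 over the remaining arrays. It was 937 with only the 8 arrays compared, 13 within slide 1 alone and 0 within slide 2 alone. Neighbouring concentrations were each on different slides. Between them, 5431 probes were called for 2000 against 500 pM, 3121 for 500 against 125 pM, 2384 for 125 against 31.2 pM and 2632 for 31.2 against 7.8 pM, with wide moves between settings: the first of these counts was 59 and the next 59 with only the 8 arrays compared, and they were 21066 and 15680 with normexp. In these 4 contrasts too the slide and the group cannot be told apart.

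Calls against the control were shared between concentrations, in contrasts that used the same 4 control arrays. The 500 and 2000 pM contrasts shared 1608 probes called in the same direction, 757 higher and 851 lower, where independent lists of these sizes would share 255.4. Simulated unchanged groups against the same controls shared a median of 0 probes, but such groups give almost no calls, so that this value does not measure the part of the shared controls. With the controls split 2 against 2, so that the contrasts had no array in common but also fewer controls each, between 308 and 502 probes were shared over the 6 ways to split them. Without control replicate 1 or 2, 913 and 1008 were shared. The log2 changes of the contrasts correlated across probes with r = 0.401, against a mean of 0.497 in simulated unchanged groups, and their covariance was 0.0674 against a simulated 0.0508. The 31.2 and 500 pM contrasts, which share slide 3 as well as the controls, had 1501 probes in common (independent lists 90.6; split controls 246 to 387), with r = 0.645 against a simulated 0.527 and a covariance of 0.111 against 0.0579. The 31.2 and 2000 pM contrasts shared 316 (independent lists 129, split controls 29 to 63). Their log2 changes correlated at r = 0.329 against a simulated 0.512, with a covariance of 0.0519 against 0.0537. With the controls split 2 against 2, r was 0.0339 to 0.076 for 31.2 and 2000 pM. It was 0.0151 to 0.227 for 500 and 2000 pM and 0.206 to 0.442 for 31.2 and 500 pM. When single arrays were left out, the shared count for 31.2 and 500 pM ran from 810 to 1675. That for 31.2 and 2000 pM ran from 145 to 608.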

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

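Apart from the comparison of 500 pM replicate 1 with its fellow arrays and the counts over other splits of the arrays, the tests in this part were chosen after the results were seen. Of 59 groups of 4 values examined for an outlying array, 4 were exceptional, where chance gives about 3.

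The E1A spike-ins, which no comparison of expression uses, were higher on slide 3 by 1.11 on the log2 scale, against an SD of 0.154 among its arrays and 0.177 among the others. This bears on the 2190 probes called at 31.2 pM, when 7.8 and 125 pM called 0. A technical difference of slide 3, such as in labelling or hybridisation, could give that shift of 1.11. The shift is, however, relative to the 75th percentile of the animals' own probes. That percentile lay at 691.2 to 1089 intensity units on slide 3 and at 476 to 789.5 on the other slides. A difference in the animals' RNA could move the ratio too and was not tested. A weaker form of the response at 2000 pM stays open. Over the probes changed at 2000 pM, the 31.2 pM change against the mean of 7.8 and 125 pM, of which 7.8 pM itself scored 0.125 along this response, had a slope of 0.00011 on the 2000 pM change (-0.019 to 0.035 when any 31.2 pM array was left out). Against the control the slope was 0.122 (r = 0.365, 68.6% of probes in the same direction), but there both changes share the control arrays. The slide could mask or mimic such a part, so that slide and exposure cannot be told apart for the 31.2 pM calls. For 500 pM, the slide alone is argued against by the score along the 2000 pM response within slide 3 (exact permutation p = 0.0143, one-sided, n = 4), while how many of its 4398 calls come from the slide stays open, as does whether the higher 75th percentile signals of the 500 pM arrays on that slide play a part.

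The array of 500 pM replicate 1 had a median Spearman correlation of 0.9316 with its group, and its deviations from the group mean had an SD of 0.7688 on the log2 scale, far from the other 3 arrays of the group. Its 75th percentile signal of 888.9 was the lowest of its group (others 1046 to 1089) and its E1A ratio of 3.18 the highest of all arrays. Dimness is argued against, however, since that signal lay above those of all arrays outside its group (476 to 830.3) and 89.14% of its probes were well above background, more than on any other 500 pM array. A swap with an array of a lower concentration on slide 3 is argued against by its score of 0.449 along the 2000 pM response, above all 31.2 pM arrays and within the range of the other 500 pM arrays. Whether its deviations were shared with the other 500 pM arrays was examined too. Low agreement with the same 3 arrays had already singled it out, so this comparison largely restates that and argues against no explanation. The deviation of replicate 1 from the 31.2 pM mean correlated across probes at -0.269 to -0.0301 with those of the other 3. Those correlated with each other at 0.362 to 0.471. A reaction to the exposure in this pool alone would not correlate either, so the test cannot decide on it. What set this array apart, in the animals of the pool, in the RNA or in its labelling and hybridisation, stays open.

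Control replicate 3 had a median Spearman correlation of 0.9815 with its group, higher than the other controls. The E1A spike-ins of 7.8 pM replicate 4 stood at 1.615 against the 75th percentile on the log2 scale, below the other 3 arrays of that group.

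Other splits of the same 8 arrays were counted for each contrast, 35 splits with the real one. For 2000 pM against the control 1 split, the real one, called as many as 6353, and the highest other, which followed the slides, called 8. For 31.2 pM (2190, highest other 3) and 500 pM (4398, highest other 8) the real split also called the most, which says nothing about the slide. The same held for 2000 against 7.8 pM (4602, highest other 380), 2000 against 500 pM (5431, highest other 862) and 500 against 125 pM (3121, highest other 4). It also held for 125 against 31.2 pM (2384, highest other 1), 31.2 against 7.8 pM (2632, highest other 4) and 500 against 31.2 pM (33, highest other 3). A share below 1 in 35 cannot be reached, and no adjustment was made for the number of contrasts. Splits that mix the groups keep a real difference inside each part, which raises the residual variance and can lower their counts. These ranks therefore do not exclude chance. For 7.8 and 125 pM, with 0 probes by limma, all 35 splits gave as many or more, up to 67 for the split of 7.8 pM and control arrays that follows the slides and 7 for 125 pM, and for 125 against 7.8 pM (0) the highest other was 1. Among 100 random orders of the 24 arrays, the real one included, 1 gave as many for the F test (10896, highest other 165) and 1 for the trend (4369, highest other 331). These orders break up slide 3 and so do not exclude the slide as a source of calls. Within slides 1 and 2, which hold no 31.2 or 500 pM arrays, the counts with the slide as a block were 4638 and 2546.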

How the results depend on the processing

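The within-slide fits, the fit without the 2 arrays of lowest weight (0.226 and 0.521), the scores and the comparisons of 500 with 31.2 pM and 125 with 7.8 pM were chosen after seeing the data. Signal over background limits the dim probes, and 4 arrays per group limit small changes. The counts of 0 at 7.8 and 125 pM held in all 15 other settings each; leaving out each array gave 0 to 1 at 7.8 pM and 0 to 1 between 125 and 7.8 pM. No direction of a named probe turned. On slide 2 alone all 4 lost their call (limma adjusted p 0.206 to 0.214) with log2 changes of 4.89, 4.63, -3.53 and -2.86; on slide 1 alone CUST_27564_PI429451402 (4.7, adjusted p = 0.189) and CUST_14938_PI429451402 (-3.05, adjusted p = 0.131) did. With normexp the change of CUST_55351_PI429451402 was -1.6 in place of -3.52. The causes were not tested. Fits of 8 arrays have fewer samples, but with only the 8 arrays compared the counts fell unevenly. At 31.2 pM the count was 1836 in place of 2190, and at 500 pM 340 in place of 4398. The number of samples therefore need not be the whole cause.

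With normexp the counts were 3387 at 31.2 pM, 19643 at 500 pM, 21066 for 2000 against 500, 15680 for 500 against 125, 7099 for 31.2 against 7.8, 74 for 500 against 31.2, 23426 in the F test and 3182 shared by 31.2 and 500 pM. For 31.2 against 7.8 pM, quantile normalization gave 1684 and the authors' values gave 1724. For 500 against 31.2 pM, median scaling gave 10, probes well above background on every array 51 and slide 3 alone 2. Array weights gave 5863 at 31.2 pM, 4874 for 125 against 31.2, 4661 for 31.2 against 7.8, 277 for 500 against 31.2, and shared counts of 2939 (31.2 and 500) and 963 (31.2 and 2000).

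With only the 8 arrays compared, counts were 340 at 500 pM, 3196 at 2000 pM, 937 for 2000 against 7.8, 59 for 2000 against 500, 59 for 500 against 125, 1016 for 125 against 31.2, 591 for 31.2 against 7.8 and 2 for 500 against 31.2. The trend over log10 concentration in exposed arrays called 2452. Split controls shared 246 to 387 (31.2 and 500), 29 to 63 (31.2 and 2000) and 308 to 502 (500 and 2000). Slide 1 alone called 16 at 2000 pM and 13 for 2000 against 7.8 pM, slide 2 alone 0 and 0. Slides 1 and 2 with the slide as a block called 4638 in the F test and 2546 for the trend. Without 500 pM replicate 1 and 2000 pM replicate 4, counts were 3974 at 31.2 pM, 3845 for 125 against 31.2, 167 for 500 against 31.2 and 562 shared by 31.2 and 2000 pM. The score of 7.8 pM was 0.11 with quantile normalization (exact p = 0.0833), 0.099 with 50 and 0.106 with 1000 probes per direction (exact p = 0.0556 in both).

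Replicate numbers were not shown to pair the arrays: deviations of same-numbered arrays correlated at 0.0143 on average (-0.451 to 0.314), and 6 of 24 arrays correlated best with their own number. With the replicate block the 500 against 31.2 pM count was 16, and 1829, 3898 and 5992 probes were called at 31.2, 500 and 2000 pM; no other count moved by over 1.5 times.

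Leaving out each array gave 1180 to 3637 at 31.2 pM, 2648 to 4646 at 500 pM, 2970 to 5404 for 2000 against 7.8, 1940 to 3239 for 500 against 125, 1299 to 3519 for 125 against 31.2, 1447 to 3352 for 31.2 against 7.8, 4 to 75 for 500 against 31.2 (where 11 of the 24 arrays each moved it by over 1.5 times), and 2659 to 4742 for the trend. Shared counts ran from 913 to 1578 (500 and 2000), 810 to 1675 (31.2 and 500) and 145 to 608 (31.2 and 2000). At 31.2 pM the count was 1215, 1180 and 1385 without control replicates 1, 2 and 3, 1431, 1351 and 1290 without its replicates 1, 2 and 4, and 3637 without 500 pM replicate 1; at 500 pM it was 2648 and 2855 without control replicates 1 and 2 and 2826 without its replicate 3. Scores ran from 0.019 to 0.274 at 7.8 pM, -0.053 to 0.069 at 125 pM and 0.6 to 0.993 at 2000 pM; these tests cannot go below exact p = 0.0556 once an array of the comparison is left out. Gene lists were not run.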

Other observations

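The tests in this part were chosen after the results were seen. Contig names that hold the letters AS, whose meaning is not given in the sources used here, marked a group of probes that changed less often at 2000 pM. Of 9942 such probes tested, 581 changed (5.84%), against 5772 of 44978 others (12.8%). Among the changed AS probes 423 rose and 158 fell, whereas among the others 2602 rose and 3170 fell. The share of rises among changed AS probes was 72.8%, where other changed probes of the same signal gave 46.1%; this difference was not tested. Nearly all AS contigs on the array (11415 of 11663) have a contig of the same name without these letters. The low share was not particular to the AS probes: in the 7647 pairs with both measured, 5.48% of the AS probes and 6.26% of their partners changed, at nearly equal signal (median difference -0.06 on the log2 scale).

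The lower share of changed AS probes has technical candidate explanations. AS probes were dimmer, with a median log2 signal of -2.87 against -1.53. Dimness as the whole cause is argued against by the count expected from other probes of the same signal, 1000.2 (10.1%), which lies above the 581 seen; the difference is -14.3 SD of a binomial count that treats probes as independent. A weaker copy of the partner's change as the source of the low share is argued against as well, since the partners changed more often by only 0.785 percentage points (binomial SD 0.348, pairs taken as independent). What makes contigs with such a partner change less often stays open. Of 479 AS probes whose partner changed at 2000 pM, 77.5% moved in the direction of the partner, with a slope of 0.343 and r = 0.423 across these pairs, and of the 96 that changed themselves 94 went the same way and 2 the opposite way. The design gives no biological explanation to test here.

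Agilent's ERCC control spots were well above background for 15.5% to 54.5% of 420 spots per array, and the 308 negative control spots for 0.325% to 3.25%. The first principal component of the arrays held 21.3% of the variance and placed 500 pM replicate 1 at 198.5, with every other array between -63.53 and 61.81.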
